A study of Homo sapiens with 54 samples.

How the data were processed

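Total RNA was sequenced in 54 libraries from LNCaP, C4-2 and 22Rv1 cells, 3 libraries in each of 18 groups (6 treatments in each line). Per the labels' protocols, cells were treated for 12 h, RNA was extracted with TRIzol, and libraries were made with a stranded total RNA kit. Groups were taken from the sample titles and, for OSU-ERb-12, from the treatment labels. One library is titled as a C4-2 vehicle library and carries the cell line tag of 22Rv1; it was kept as C4-2 vehicle library 1, and its correlation with C4-2 was 0.9982 against 0.8496 with 22Rv1. The latter is the highest of the 18 C4-2 libraries, the others lying between 0.8414 and 0.8465; with C4-2 the others lay between 0.9964 and 0.9988. The titles mark the OSU-ERb-12 groups by the letters WT, whose meaning the labels do not give. That these groups received OSU-ERb-12 therefore rests on the treatment labels.

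The submitters' processing notes name FastQC, Trimmomatic, featureCounts and edgeR and the hg38 build, and the series' design text names Rsubread; their versions are not given in the sources used here. Per the labels the table is in CPM (counts per 1000000 reads), but the deposited values are a score: log2 CPM with 0.5 reads added, divided by a factor per library so that each column sums to 1000000, and 24.3 to 30.1% of the values per library are negative. This reading comes from the values themselves. From the deposited log2 values whole reads were recovered for 100% of values (largest distance from a whole number 0.0041, tolerance 0.01). Depth was 32819568 to 52417050 reads in genes per library, 0.895 to 1.105 times the authors' effective library sizes, and between 519 and 1282 of the 19225 genes and other transcripts had 0 reads in a library. Gene IDs were matched to RefSeq GRCh38.p14 for 18917 of them, 306 had no symbol, and coordinates are from that annotation. Genes with near-identical copies, such as the UGT2B family and the histone genes, share reads and are uncertain.

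CPM was computed from the recovered reads and the authors' effective sizes. The test was limma (3.58.1, R 4.3.3) with a mean-variance trend on log2(CPM + 0.5), so that log2 fold changes understate the change of low genes. Genes with at least 1 CPM in at least 3 libraries of a fit entered it. Each line was fitted alone (18 libraries, 12 residual degrees of freedom), and lines were compared in a fit of all 54. P-values are two-sided, adjusted by Benjamini-Hochberg within a comparison, and called at 0.05. Interactions were tested as the effect of an agent with Enza minus its effect without it, and differences between lines by an F test over the 3 lines.

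Gene lists were tested with camera (limma) at a preset correlation of 0.01, adjusted over 28 lists and 18 comparisons, and again with an estimated correlation; lists with fewer than 5 measured members had no set test. The lists reported are ER-activated, steroid receptors, G1/S and DNA replication, G2/M and mitosis, cholesterol synthesis and uptake, fatty acid synthesis, unfolded protein response, amino acid stress (ATF4), NF-kappaB, interferon, TGF-beta, hypoxia and glycolysis, p53, neuroendocrine, immediate early, aryl hydrocarbon receptor, heat shock, oxidative stress (NRF2), glucocorticoid-shared, luminal prostate, basal or squamous epithelium, fibroblast or mesenchyme, leukocyte, mitochondrially encoded mRNA, replication-dependent histones and cytosolic ribosomal proteins. Some list members, among them ESR1, were not analysed here, and some genes and lists are not reported here.

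Named genes followed a rule. In each comparison of 1 agent with vehicle these were the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among called genes with a symbol, a mean of at least 1 CPM, and all 3 libraries of one group above all 3 of the other. Other comparisons took 5 each way. Genes set beforehand, such as KLK3, KLK2, TMPRSS2, FKBP5 and ESR2, and up to 4 members with the smallest p of each list described, were added. The groups, the tests, the lists, this rule, and the alternatives of another pseudocount, no filter, TMM rescaling, a block for the replicate number, 1 fit of all libraries, an estimated correlation, fry and leaving out each library were fixed before the data were examined. TMM factors were computed with a function written in R. A count test in edgeR was planned and not run, because the deposited unit is not counts; voom weights on the recovered reads took its place. Voom, scaling to total reads, cyclic loess, leaving out the libraries that stand apart, the mean OSU effect over lines and the comparison of E2+Enza with E2 were chosen after seeing the data.

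The libraries that stand apart are C4-2 vehicle 1, C4-2 E2 3 and 22Rv1 vehicle 3, the last 2 with high mitochondrial ribosomal RNA, and 22Rv1 OSU+Enza 2, with a high share of small RNA (4.04% of reads). They were picked by inspection and not by a rule. The library 22Rv1 Enza 3 has a higher share of small RNA (4.36%) and was not among them; it was left out in the fits without 1 library. The spread between replicates was 2.18 to 4.8 times counting noise over 54 pairs. That noise takes each read as an independent count, which was not tested. Even numbers made up 54.1 to 58.8% of the values under 100 reads per library, and the cause of this share was not tested. The ratio therefore does not decide whether any pair matched within counting noise. The fits were tested on simulated data with 200 changed genes per line for E2 against vehicle, drawn at the real levels and depths. There were 7, 11 and 11 false calls in LNCaP, C4-2 and 22Rv1. Each gene was drawn independently, so these numbers do not cover deviations that many genes of a library share. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.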

Results

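RNA was measured by sequencing in 54 libraries from 3 human prostate cancer cell lines. LNCaP is a hormone-responsive line from a lymph node metastasis, C4-2 is a derivative of LNCaP that grows in castrated hosts, and 22Rv1 comes from a relapsed xenograft. Each line received vehicle (ethanol), 17-beta-estradiol (E2, 100 nM), OSU-ERb-12 (OSU, 100 nM), the prostate cancer drug enzalutamide (Enza, 1 µM), E2 with Enza, or OSU with Enza, for 12 h in medium with 10% serum. The series title names the functions of estrogen receptor beta (ER-beta, gene ESR2) in prostate cancer as its subject. There were 3 libraries per group, biological triplicates per the labels, in 18 groups. The deposited values decode to 32819568 to 52417050 reads per library over 19225 genes and other transcripts, so that 1 read was worth 0.0204 to 0.0323 counts per 1000000 reads (CPM). The value after ± is the SD of 3 libraries for a level in CPM and the SE for a log2 fold change, with n = 3 libraries per group throughout.

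The 3 lines differed in most genes before any treatment, and ESR2 was low in all of them. ESR2 (chromosome 14, 64226707 to 64338613 on GRCh38.p14) lay between 1.22 and 3.08 CPM, or 47 to 134 reads, over the 54 libraries. Its vehicle levels were 2.16 ± 0.469 CPM in LNCaP, 1.93 ± 0.1 in C4-2 and 2.31 ± 0.279 in 22Rv1, with no call between lines (adjusted p = 0.514 and 0.587 against LNCaP). KLK3 (chromosome 19, 50854915 to 50860764), which encodes prostate-specific antigen, stood at 1110 ± 37 CPM in LNCaP, 2130 ± 40.1 in C4-2 and 9.57 ± 1.62 in 22Rv1, a log2 difference of -6.80 ± 0.07 between 22Rv1 and LNCaP. Against LNCaP, C4-2 was higher in DPP4, a cell-surface peptidase (6.16 ± 0.12), and BMP7, a secreted growth factor (5.81 ± 0.11), and lower in ETV1, an ETS transcription factor (-9.26 ± 0.14), and TWIST1 (-5.28 ± 0.10). The line 22Rv1 was higher than LNCaP in the receptor EPHA3 (8.57 ± 0.15) and the protease inhibitor SPINK1 (8.47 ± 0.18) and lower in the secreted protein SPON2 (-8.50 ± 0.08) and the Notch ligand JAG1 (-6.95 ± 0.11). The limma test called 10697 of 16026 genes between C4-2 and LNCaP (5452 higher, 5245 lower) and 13355 between 22Rv1 and LNCaP (6470 higher, 6885 lower). Scaling to total reads moved the median of all genes between C4-2 and LNCaP to -0.102 and the split to 3933 higher and 6672 lower.

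E2 in LNCaP raised FKBP5, MAF, TMPRSS2, KLK2 and KLK3. FKBP5 (chromosome 6, 35573590 to 35728583), a co-chaperone of steroid receptors, rose from 173 ± 8.49 to 1020 ± 8.36 CPM (log2 fold change 2.56 ± 0.06), and the transcription factor MAF from 52.8 ± 2.8 to 351 ± 10.2 CPM (2.72 ± 0.06). TMPRSS2 (chromosome 21, 41464305 to 41508158), a membrane serine protease, rose by 1.35 ± 0.03. KLK2 (chromosome 19, 50873439 to 50880567), a prostate kallikrein, rose by 0.98 ± 0.04, and KLK3 by 0.50 ± 0.04. By fold, the leading genes included the amino acid transporter SLC38A4 (3.65 ± 0.15), CCDC141 (3.39 ± 0.15), the metalloreductase STEAP4 (3.24 ± 0.18), the glucose transporter SLC2A3 (3.24 ± 0.20) and the kinase SGK1 (2.69 ± 0.13). Among genes that fell were the kinase DAPK1 (8.56 ± 0.578 to 1.27 ± 0.177 CPM, -2.36 ± 0.10), CBLN2 (-1.71 ± 0.08), LRRN1 (-1.58 ± 0.08), the kappa opioid receptor OPRK1 (-1.50 ± 0.11) and the cholesterol exporter ABCA1 (-1.46 ± 0.15). ESR2 was not called (-0.20, 95% interval -0.53 to 0.12). In all, 3551 of 14251 genes were called, 1894 higher and 1657 lower, of which 133 by at least 2-fold (107 higher, 26 lower). The split depended on scaling, with 1148 higher and 2657 lower at total read scaling.

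By gene list, the glucocorticoid-shared list, genes that several steroid receptors can induce, had 10 of 12 higher (median 0.56, 10 adjusted over the list alone; adjusted p = 0.000738 with an estimated correlation), led by FKBP5, the EGFR inhibitor ERRFI1 (1.51) and SGK1. Of the unfolded protein response list, 15 of 16 rose, also 15 adjusted over the list alone, by a median of 0.30, among them the endoplasmic reticulum chaperone HSPA5 (0.36 ± 0.03) and HERPUD1 (0.47 ± 0.04); adjusted p = 0.0239 with an estimated correlation. The p53 list went the other way, with 14 of 18 lower and 1 higher (1 higher and 16 lower adjusted over the list alone; median -0.25; adjusted p = 0.0124 with an estimated correlation). TP53INP1 (-0.90 ± 0.03) and SESN1 (-0.60 ± 0.04) fell and the death receptor TNFRSF10B rose (0.39 ± 0.03). The luminal prostate list had 9 higher and 4 lower of 14, or 10 higher and 4 lower adjusted over the list alone (adjusted p = 0.0703 with an estimated correlation). In LNCaP, genes that estradiol induces through ER in other tissues did not move as a group. The ER-activated list had 4 higher and 7 lower of 17 there (4 higher and 8 lower adjusted over the list alone, median -0.02, mean 0.02). Its set test by camera gave adjusted p = 0.836, set direction down. Within it GREB1 rose (1.51 ± 0.09) and the progesterone receptor gene PGR fell (-1.04 ± 0.20).

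E2 in C4-2 again raised FKBP5, TMPRSS2 and the kallikrein genes. FKBP5 rose from 227 ± 7.97 to 612 ± 40.2 CPM (1.42 ± 0.05), SLC45A3, a prostate solute carrier, from 77.3 ± 4.08 to 220 ± 8.69 CPM (1.50 ± 0.06), TMPRSS2 by 0.78 ± 0.05, KLK2 by 0.67 ± 0.04 and KLK3 by 0.27 ± 0.05. CCDC141 (2.18 ± 0.16), the nicotinic receptor subunit CHRNA2 (2.00 ± 0.12) and MAF (1.75 ± 0.14) led by fold. The phospholipase PLD1 (-1.20 ± 0.09), WNT5A (-0.91 ± 0.09) and the chemokine receptor ACKR3 (-0.85 ± 0.06) were among those that fell most. The glucocorticoid-shared list had 6 higher and 1 lower of 12, or 7 higher and 3 lower adjusted over the list alone (adjusted p = 0.00217 with an estimated correlation). Unfolded protein response genes were 5 higher and 0 lower of 16 (9 higher adjusted over the list alone; adjusted p = 4.4e-07, and adjusted p = 0.288 with an estimated correlation). The test called 817 of 14027 genes, 381 higher and 436 lower, 35 of them by at least 2-fold. The count was 541 without vehicle library 1, whose cell line tag disagrees with its title, and 521 without E2 library 3, which has more mitochondrial ribosomal RNA than the rest of its group. The split was 525 higher and 342 lower after cyclic loess and 252 higher and 144 lower without both of these libraries.

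E2 in 22Rv1 again raised FKBP5, TMPRSS2 and the kallikrein genes, while immediate early genes fell. FKBP5 rose from 160 ± 1.32 to 745 ± 23.5 CPM (2.22 ± 0.05), SLC45A3 by 2.07 ± 0.06, KLK2 by 1.15 ± 0.06 and TMPRSS2 by 0.62 ± 0.08, and KLK3 rose from its low 9.57 ± 1.62 CPM to 19.7 ± 3.09 (1.01 ± 0.11). CHRNA2 (2.79 ± 0.08), TMCC3 (2.36 ± 0.08), SLC38A4 (2.30 ± 0.12) and the acyltransferase MBOAT2 (2.16 ± 0.07) were among those that rose most. The transcription factors EGR1 (230 ± 14.3 to 100 ± 9.18 CPM, -1.20 ± 0.08), FOS (-1.29 ± 0.09), FOSB (-1.60 ± 0.15) and EGR3 (-1.31 ± 0.14) fell, as did the GABA receptor subunit GABRE (-1.63 ± 0.11). Of the immediate early list, 9 of 14 fell and 0 rose (11 lower adjusted over the list alone; median -0.40; adjusted p = 0.0188 with an estimated correlation). The glucocorticoid-shared list had 9 higher and 1 lower of 12 (10 higher and 1 lower adjusted over the list alone; median 0.93; adjusted p = 0.000195 with an estimated correlation).

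Members of 4 other lists were called as higher by small amounts with E2 in 22Rv1, and no set call held with an estimated correlation (adjusted p = 0.406 for replication-dependent histones, 0.355 for G1/S and DNA replication, 0.305 for cholesterol and 0.185 for the unfolded protein response). Replication-dependent histone genes were higher in 17 of 18, also 17 adjusted over the list alone (median 0.29). G1/S and DNA replication genes were higher in 16 of 25 (18 adjusted over the list alone; median 0.18). The cyclin CCNE2 rose by 0.48 ± 0.05 and RRM2, a subunit of ribonucleotide reductase, by 0.36 ± 0.05. Cholesterol synthesis and uptake genes were higher in 13 of 20 (17 adjusted over the list alone; median 0.17), and unfolded protein response genes in 14 of 16 (16 adjusted over the list alone; median 0.25). The counts were smaller at other scalings: after cyclic loess 10 histone, 9 G1/S and 4 cholesterol genes were called as higher (medians 0.18, 0.09 and 0.09), and at total read scaling 14, 8 and 4 (0.22, 0.11 and 0.10). With E2 in LNCaP and C4-2, G1/S genes had 3 higher and 3 lower and 0 higher and 1 lower (adjusted p = 0.974 and 0.154), histone genes 0 higher and 0 lower in both (0.211 and 0.216), and cholesterol genes 9 higher and 0 lower of 19 and 1 higher and 1 lower (0.000141 and 0.178; adjusted p = 0.349 in LNCaP with an estimated correlation). Adjusted over the list alone, they had 3 higher and 3 lower and 0 higher and 3 lower, 0 higher and 0 lower in both, and 9 higher and 0 lower and 1 higher and 1 lower. Histone genes were called as a set in LNCaP without vehicle library 3 (adjusted p = 0.00399) and, as lower, in C4-2 without vehicle library 3 (0.0452) or E2 library 2 (0.0111). Cholesterol genes were called in C4-2 without E2 library 3 (0.034), after cyclic loess (0.0247) and without the libraries that stand apart (0.0111). The limma test called 4118 of 14866 genes, 2540 higher and 1578 lower, but 81 by at least 2-fold. The count was 2193 without vehicle library 1, 2598 without E2 library 1 and 2565 without E2 library 2. The direction of the excess turned with scaling, to 1007 higher and 2131 lower at total read scaling and 1365 higher and 1642 lower after cyclic loess.

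Set side by side, the E2 responses of the lines shared genes and differed in size. Of 12970 genes tested in every line, 273 were called in all 3, 175 higher in each and 49 lower in each. LNCaP and C4-2 had 575 genes called in both, 556 in the same direction (296 higher where independent lists would give 49.5, and 260 lower against 50), and LNCaP and 22Rv1 had 1396, 1276 in the same direction (873 higher against 326, and 403 lower against 155). C4-2 and 22Rv1 had 339 in both and 243 in the same direction (186 higher against 62.5, and 57 lower against 40.7). The correlation of all their log2 fold changes was near 0 (r = -0.02 across 13201 genes, which are not independent replicates). With E2, fold change followed mean expression level in opposite directions in C4-2 and 22Rv1 (r = -0.18 and 0.3). How far this sets that correlation was not tested. A test of the difference itself called 4671 of 16026 genes. The E2 effect on FKBP5 was -1.13 in C4-2 relative to LNCaP (log2; adjusted p = 6.41e-16), and that on MAF was -1.41 in 22Rv1 relative to LNCaP (adjusted p = 4.5e-08). The effect on KLK3 was higher by 0.73 in 22Rv1 than in C4-2 (adjusted p = 8.21e-07), and that on EGR1 was -1.12 in 22Rv1 relative to LNCaP (adjusted p = 0.000219). DAPK1, which fell in LNCaP, differed by 2.33 between 22Rv1 and LNCaP (adjusted p = 3.14e-17). Without C4-2 E2 library 3 the count was 2952.

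Enza in LNCaP lowered the kallikrein genes, TMPRSS2 and FKBP5. KLK2 fell from 178 ± 4.78 to 51.7 ± 3.37 CPM (-1.77 ± 0.04). TMPRSS2 (-1.64 ± 0.03), KLK3 (-1.17 ± 0.04) and FKBP5 (-0.60 ± 0.06) also fell. CHRNA2 (9.61 ± 0.453 to 0.76 ± 0.1 CPM, -3.01 ± 0.09), CCDC141 (-2.62 ± 0.15) and the cold-sensing channel TRPM8 (-2.21 ± 0.09) were among those that fell most. OPRK1 (3.83 ± 0.442 to 12.5 ± 0.547 CPM, 1.59 ± 0.11), the mannosidase MAN1A1 (1.34 ± 0.10) and ABCA1 (1.27 ± 0.15) were among those that rose most. The p53 list had 8 higher and 0 lower of 18, with the same numbers adjusted over the list alone (adjusted p = 8.27e-05, and adjusted p = 0.0647 with an estimated correlation), with TP53INP1 at 0.64 ± 0.03 and the cell cycle inhibitor CDKN1A at 0.34 ± 0.04. G1/S and DNA replication genes had 0 higher and 11 lower of 25, likewise adjusted over the list alone (median -0.09; adjusted p = 2.73e-06, and adjusted p = 0.362 with an estimated correlation). In all 2911 genes were called, 1395 higher and 1516 lower, 67 by at least 2-fold.

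In C4-2, Enza lowered SLC45A3 from 77.3 ± 4.08 to 16.8 ± 0.556 CPM (-2.17 ± 0.06). PMEPA1, a brake on TGF-beta signalling (-1.81 ± 0.04), TMPRSS2 (-1.47 ± 0.05), KLK2 (-0.87 ± 0.04), FKBP5 (-0.53 ± 0.05) and KLK3 (-0.52 ± 0.05) fell too. WNT5A (1.11 ± 0.09) and the transcription factor SOX9 (0.90 ± 0.07) rose. The unfolded protein response list had 0 higher and 14 lower of 16, likewise adjusted over the list alone (HSPA5 -0.46 ± 0.04; adjusted p = 8.59e-15, and adjusted p = 0.0842 with an estimated correlation). Mitochondrially encoded mRNA had 10 higher and 0 lower of 13 (12 higher adjusted over the list alone; adjusted p = 0.305 with an estimated correlation). The test called 1184 genes, 383 higher and 801 lower, a split of 742 higher and 496 lower at total read scaling and 530 higher and 698 lower after cyclic loess. The count was 640 without vehicle library 1, 770 without vehicle library 2, 609 without Enza library 2 and 698 without Enza library 3.

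In 22Rv1, few genes were called with Enza, and kallikrein and immediate early genes were among those that fell. By limma 2198 genes had an unadjusted p under 0.05, where chance gives 743. The count of calls therefore does not measure how many genes changed. PMEPA1 fell from 30.2 ± 1.33 to 14.1 ± 0.544 CPM (-1.07 ± 0.07), as did CHRNA2 (-1.11 ± 0.08), MBOAT2 (-1.05 ± 0.07) and KLK2 (-0.76 ± 0.06). KLK3 (-0.62 ± 0.11) and FKBP5 (-0.28 ± 0.05) fell too. TMPRSS2 was not called (-0.04, 95% interval -0.20 to 0.13). EGR1 (-0.83 ± 0.08), EGR3 (-1.15 ± 0.14) and FOS (-0.73 ± 0.09) fell, as they did with E2. The immediate early list had 0 higher and 6 lower of 14, or 1 higher and 10 lower adjusted over the list alone (adjusted p = 0.00464 with an estimated correlation). The glucocorticoid-shared list had 0 higher and 3 lower of 12, or 0 higher and 6 lower adjusted over the list alone (adjusted p = 0.001 with an estimated correlation). Of 14866 genes tested 98 were called, 25 higher and 73 lower, or 9 higher and 111 lower at total read scaling and 79 higher and 110 lower in a fit of all 54 libraries. The count was 58 without vehicle library 1, 59 without vehicle library 2, 60, 55 and 410 without Enza libraries 1, 2 and 3.

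Between lines, the Enza effect differed for 2125 of 16026 genes. In 22Rv1 relative to LNCaP the effect was 1.60 for TMPRSS2 (log2; adjusted p = 1.03e-22) and 1.89 for CHRNA2 (adjusted p = 3.02e-15), and relative to C4-2 it was 1.53 for SLC45A3 (adjusted p = 1.16e-19). All 3 lines shared 35 calls, 4 higher and 30 lower in each. The count of differing genes was 1388 without 22Rv1 vehicle library 1, 1262 without C4-2 vehicle library 1 and 1229 without C4-2 Enza library 2.

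**Figure D1:**
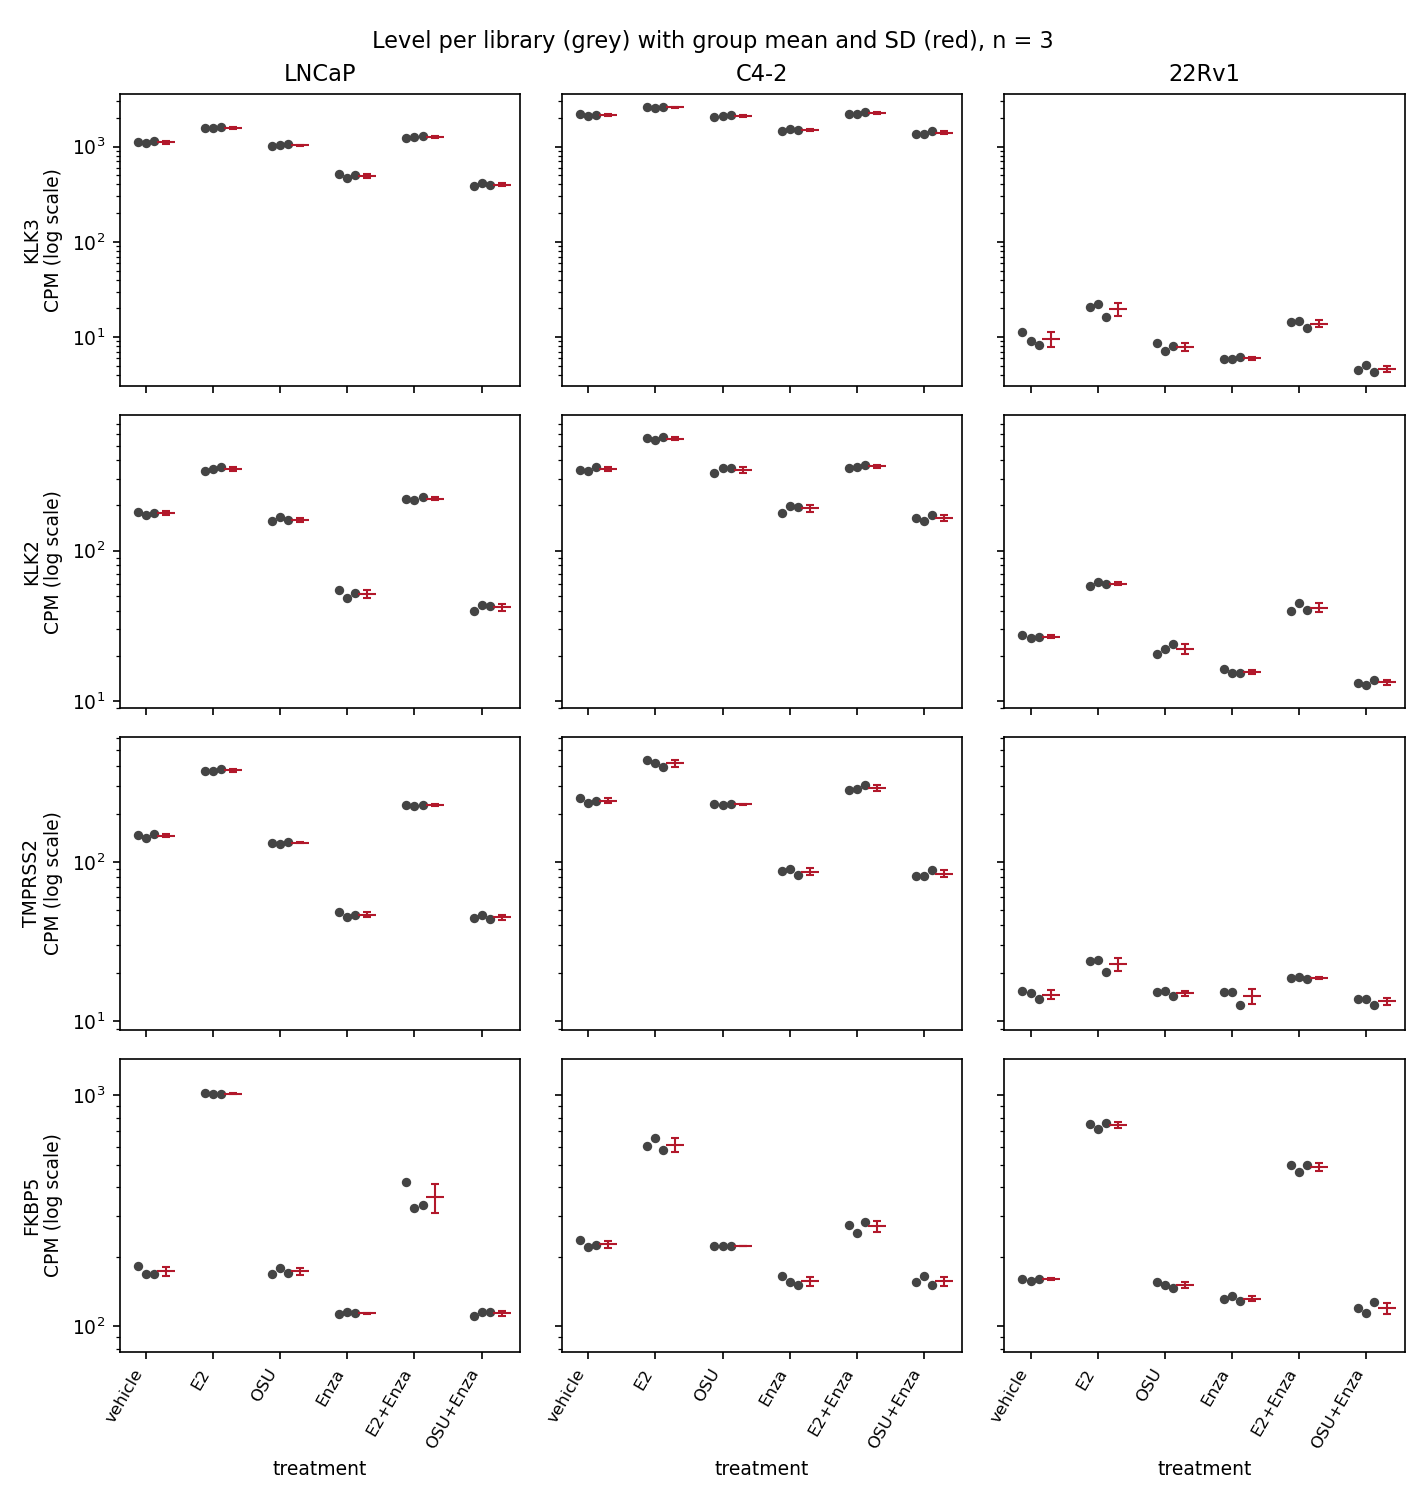
Level of KLK3, KLK2, TMPRSS2 and FKBP5 in CPM (log axis, its range set per gene and shared by the lines) in each of the 54 libraries, by line and treatment; grey points are libraries and red bars the group mean and SD (n = 3). All 4 genes are higher with E2 than with vehicle in each line, and FKBP5 in LNCaP is at 173 ± 8.49 CPM with vehicle and 1020 ± 8.36 CPM with E2.

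Genes called with both E2 and Enza mostly moved in opposite directions. In LNCaP 1355 genes were called with both agents and 1009 of them (74.5%) moved oppositely, 525 higher with E2 and lower with Enza where independent lists would give 201, and 484 the reverse against 162. In C4-2 it was 305 of 341 (89.4%) and in 22Rv1 57 of 74 (77.0%). Over all genes tested the log2 fold changes had r = -0.31 and a covariance of -0.0172 in LNCaP, r = 0.02 and 0.000513 in C4-2, and r = 0.32 and 0.0108 in 22Rv1. Fold changes also followed mean expression level. With it, r was 0.1 for E2 and 0.09 for Enza in LNCaP, -0.18 and -0.25 in C4-2, and 0.3 and 0.23 in 22Rv1. The part of this trend in the correlation of E2 with Enza was not tested. Unchanged groups with a shared control were simulated from deviations of libraries drawn from all groups of a line, not from vehicle alone. They gave mean r of 0.50, 0.47 and 0.50, with 95% of the draws from 0.13 to 0.77, 0.05 to 0.77 and 0.19 to 0.73. Their mean covariances were 0.00489, 0.0051 and 0.00568, with 95% of the draws from 0.00105 to 0.00917, 0.000459 to 0.012 and 0.00137 to 0.0108. In LNCaP both observed values lay below these ranges, in C4-2 r lay below and the covariance within, and in 22Rv1 r lay within and the covariance at the upper end. The observed covariance minus the mean simulated one was -0.0221 in LNCaP, -0.00459 in C4-2 and 0.00512 in 22Rv1. Because vehicle has 3 libraries that cannot be divided into parts of 2, part of any excess of calls in the same direction may come from the shared controls.

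E2 in the presence of Enza still raised genes that Enza alone lowered. Against Enza alone, E2+Enza raised CHRNA2 in LNCaP from 0.76 ± 0.1 to 23.8 ± 2.09 CPM (4.27 ± 0.09) and KLK3 by 1.35 ± 0.04. In C4-2, SLC45A3 rose from 16.8 ± 0.556 to 108 ± 8.44 CPM (2.65 ± 0.06) and PMEPA1 by 2.21 ± 0.04. In 22Rv1 CHRNA2 rose by 3.28 ± 0.08, MBOAT2 by 2.78 ± 0.07 and FKBP5 by 1.89 ± 0.05. OPRK1 (-2.54 ± 0.11) in LNCaP, WNT5A (-1.30 ± 0.09) in C4-2 and the matricellular gene CCN3 (-1.44 ± 0.09) in 22Rv1 fell. The glucocorticoid-shared list had 7 higher and 2 lower of 12 in LNCaP, 5 higher and 0 lower of 12 in C4-2 and 9 higher and 0 lower of 12 in 22Rv1. Adjusted over the list alone the counts were 8 higher and 2 lower, 6 higher and 0 lower and 9 higher and 0 lower (adjusted p = 0.0124, 0.00486 and 5.53e-05 with an estimated correlation). In all, 3291 genes were called in LNCaP (1733 higher, 1558 lower), 1035 in C4-2 (622 and 413) and 1180 in 22Rv1 (611 and 569). At total read scaling the split was 1247 higher and 1729 lower in LNCaP and 553 higher and 655 lower in C4-2.

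Against vehicle, FKBP5 had a higher mean with E2+Enza in each line, and few genes were called in C4-2. FKBP5 was higher than vehicle by 1.05 ± 0.06 in LNCaP and 1.61 ± 0.05 in 22Rv1. In C4-2 it stood at 271 ± 15.1 CPM with E2+Enza and 227 ± 7.97 CPM with vehicle. In C4-2 the calls were 11 (6 higher, 5 lower), with CHRNA2 (0.81 ± 0.12), SLC45A3 (0.48 ± 0.06) and PMEPA1 (0.39 ± 0.04) among those higher (CHRNA2 was not called without vehicle library 2, 0.74) and the scavenger receptor gene COLEC12 (-0.36 ± 0.06) among those lower. Their split was 14 higher and 6 lower at total read scaling and 4 higher and 5 lower without the filter on low values. LNCaP had 1058 calls (644 higher, 414 lower; 333 higher and 440 lower at total read scaling) and 22Rv1 2055 (1204 higher, 851 lower; 438 higher and 1530 lower at total read scaling and 852 higher and 1052 lower after cyclic loess). Single libraries moved these counts: LNCaP had 682 without vehicle library 2, 568 without E2+Enza library 1 and 653 without E2+Enza library 2. C4-2 had 6, 3 and 4 without vehicle libraries 1, 2 and 3 and 34 without E2+Enza library 3, and 22Rv1 had 856 without vehicle library 1, 1189 without vehicle library 2 and 886 without E2+Enza library 3.

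The interaction of E2 with Enza, the E2 effect with Enza minus the E2 effect without it, went in different directions for different genes. KLK2 had a positive interaction in LNCaP (1.12 ± 0.06), where FKBP5 (-0.91 ± 0.08), SGK1 (-2.31 ± 0.19) and NDRG1 (-1.74 ± 0.15) had negative ones. FKBP5 was also negative in C4-2 (-0.64 ± 0.07). In 22Rv1 FOS (1.44 ± 0.13), FOSB (1.54 ± 0.21) and EGR1 (0.92 ± 0.11) had positive interactions. The test called 1290 genes in LNCaP (643 higher, 647 lower), 210 in C4-2 (148 and 62) and 63 in 22Rv1 (20 and 43). At total read scaling the splits were 660 higher and 359 lower in LNCaP, 107 higher and 78 lower in C4-2 and 20 higher and 19 lower in 22Rv1, and after cyclic loess 132 higher and 105 lower in C4-2 and 25 higher and 34 lower in 22Rv1. The C4-2 count was 130 without vehicle library 1, 88 higher and 28 lower without E2 library 3, 106 and 132 without Enza libraries 2 and 3, and 332 and 131 without E2+Enza libraries 2 and 3. The 22Rv1 count was 26 and 32 without vehicle libraries 1 and 2, 26 without E2 library 1 and 26 without E2 library 2. It was 35, 21 and 350 without Enza libraries 1, 2 and 3, and 28, 29 and 335 without E2+Enza libraries 1, 2 and 3.

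**Figure D2:**
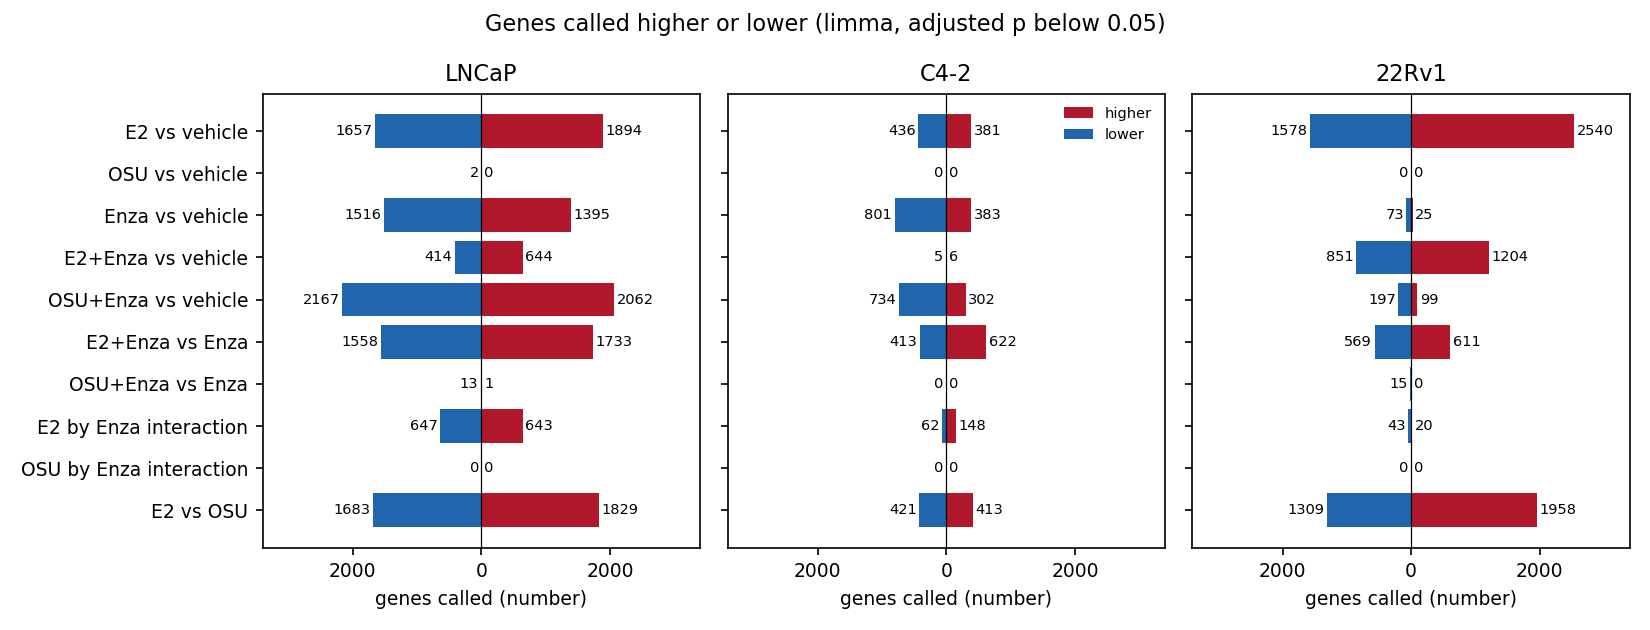
Number of genes called higher (red, right) and lower (blue, left) by limma in each comparison within a line. Calls number 3551, 817 and 4118 for E2 in LNCaP, C4-2 and 22Rv1, 0 to 2 for OSU alone and 0 to 15 for OSU added to Enza.

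With OSU alone almost no gene was called at 3 libraries per group, which does not show that no gene changed. In LNCaP TM4SF1, a tetraspanin-like membrane protein, fell from 42.4 ± 2.72 to 33.8 ± 1.98 CPM (-0.32 ± 0.06). SYT4, a synaptotagmin, fell there from 130 ± 3.86 to 112 ± 1.29 CPM (-0.21 ± 0.04). Both were at adjusted p = 0.0392 by limma, and no gene was called as higher. KLK3 stood at -0.11 (95% interval -0.19 to -0.03) in LNCaP, -0.03 (-0.13 to 0.06) in C4-2 and -0.25 (-0.47 to -0.02) in 22Rv1 and FKBP5 at 0.00 (-0.12 to 0.11), -0.03 (-0.13 to 0.07) and -0.08 (-0.18 to 0.01), none called. By limma 2 genes were called in LNCaP, 0 in C4-2 and 0 in 22Rv1, with 946, 396 and 298 at an unadjusted p under 0.05 where chance gives 713, 701 and 743; voom called 0, 0 and 0. The numbers under chance in C4-2 and 22Rv1 come from a test whose spread was pooled over all groups of a line. Whether this made the test strict for OSU was not tested. The LNCaP calls were 12 without vehicle library 1 and 0 without vehicle library 2 or 3 or without OSU library 1, 2 or 3. The OSU effect differed between lines for 0 of 16026 genes by limma (471 at an unadjusted p under 0.05, chance 801; 0 by voom), and for 1 without LNCaP vehicle library 1 or without C4-2 vehicle library 3. In simulated data for E2 against vehicle with the real levels and depths, the same test recovered 60% of genes changed by 1.25-fold and 90% of those changed by 1.5-fold in LNCaP, 56% and 80% in C4-2, and 62% and 90% in 22Rv1. Those data had 200 genes changed in E2 and none in OSU, with each gene drawn independently. The Benjamini-Hochberg adjustment is stricter where few genes change, so these rates do not give the power for OSU.

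By list, mitochondrially encoded mRNA had medians below 0 with OSU in each line: -0.12, -0.11 and -0.15 in LNCaP, C4-2 and 22Rv1. The set call was lost in each line with an estimated correlation (adjusted p = 0.633, 0.362 and 0.362) and with fry (adjusted p = 0.555, 0.264 and 0.364). No member was called, over all genes or adjusted over the list alone. Mitochondrial ribosomal RNA, chosen after its values were seen, was not called but had lower means too: RNR2 stood at 420 ± 76 CPM with vehicle and 300 ± 168 with OSU in LNCaP, 442 ± 22.6 and 261 ± 89.2 in C4-2, and 673 ± 537 and 211 ± 131 in 22Rv1. For RNR1 it was 62.6 ± 9.58 and 43.4 ± 13.9, 76.1 ± 5.59 and 43.5 ± 8.91, and 215 ± 281 and 33 ± 9.03 CPM. The 22Rv1 vehicle means rest on library 3, with 1270 CPM of RNR2 and 539 CPM of RNR1, against 231 and 516 CPM of RNR2 and 38.7 and 67.7 CPM of RNR1 in libraries 1 and 2. With the preset correlation the mitochondrial set was not called without LNCaP vehicle library 1 (adjusted p = 0.137) or OSU library 1 (0.204), nor without C4-2 vehicle library 2 (0.0593) or OSU library 3 (0.161). The glucocorticoid-shared list in 22Rv1 was lower as a set (median -0.08, no member called either way; adjusted p = 0.0247 with an estimated correlation). The ER-activated list had no set call in LNCaP (median -0.01, adjusted p = 0.694), C4-2 (0.00, 0.684) or 22Rv1 (-0.01, 0.17), with 0 members called in each and 1 lower in 22Rv1 adjusted over the list alone; without 22Rv1 vehicle library 1 the 22Rv1 set was called (adjusted p = 0.0344).

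Added to Enza, OSU lowered a few genes. In LNCaP KLK3 fell from 494 ± 23.4 to 398 ± 12.4 CPM (-0.31 ± 0.04), as did KLK2 (-0.29 ± 0.04), SYT4 (-0.37 ± 0.04), NAV3, a neuronal guidance gene (-0.53 ± 0.08) and the collagen COL12A1 (-0.36 ± 0.06), and FAM43A rose (0.20 ± 0.04). In 22Rv1 SYT4 (-0.39 ± 0.07) and the growth factor IGF1 (-0.36 ± 0.07) fell. Without any one of Enza libraries 1 and 2 or OSU+Enza libraries 1, 2 and 3, FAM43A was not called in LNCaP (0.18 to 0.22). In 22Rv1 SYT4 was not called without Enza library 1 or 2 or OSU+Enza library 1 (-0.35 to -0.39), nor IGF1 without Enza library 1, 2 or 3 or OSU+Enza library 1 or 2 (-0.30 to -0.38). The calls were 1 higher and 13 lower in LNCaP, 0 in C4-2 and 0 higher and 15 lower in 22Rv1 (3 higher and 19 lower after TMM rescaling, 3 higher and 25 lower after cyclic loess, 14 higher and 72 lower in a fit of all 54 libraries). For the 0 in C4-2, limma had 971 genes at an unadjusted p under 0.05 with a smallest adjusted p of 0.0517, and voom called 2. The LNCaP count was 9 without Enza library 1 and 6 without OSU+Enza library 1, and the C4-2 count 1 without OSU+Enza library 1 or 3. In 22Rv1 it was 0 without Enza library 1 or without OSU+Enza library 1, 1 and 26 without Enza libraries 2 and 3, and 7 without OSU+Enza library 2. Mitochondrially encoded mRNA had medians of -0.28 in LNCaP and -0.23 in C4-2, and 0.01 in 22Rv1, with 0 called. Adjusted over the list alone, 12 were lower in LNCaP and 10 in C4-2 (adjusted p = 0.253, 0.175 and 0.96 with an estimated correlation). RNR2, chosen after its values were seen and not called, stood at 472 ± 104 CPM with Enza and 347 ± 36.8 with OSU+Enza in LNCaP, 283 ± 231 and 307 ± 122 in C4-2 (log2 fold change 0.33, and -0.14 without Enza library 3), and 423 ± 292 and 623 ± 161 in 22Rv1. With the preset correlation the 22Rv1 set was called without Enza library 2 (adjusted p = 0.0118) or OSU+Enza library 2 (0.00616), and in the other direction without Enza library 3 (0.00676).

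Against vehicle, OSU+Enza lowered KLK2 in LNCaP (-2.07 ± 0.04), TMPRSS2 in C4-2 (-1.52 ± 0.05) and PMEPA1 in 22Rv1 (-1.33 ± 0.07). The counts were 4229 in LNCaP (2062 higher, 2167 lower), 1036 in C4-2 (302 and 734; 499 higher and 688 lower at total read scaling) and 296 in 22Rv1 (99 and 197; 49 higher and 385 lower at total read scaling). In 22Rv1 the spliceosomal RNA RNU4-2 rose from 25.6 ± 2.82 to 47.4 ± 9.49 CPM (0.86 ± 0.15). OSU+Enza library 2 has the highest share of small RNA of its group. Of 7 small nuclear and nucleolar RNAs called as higher, 1 was still called without it, RNU4-2 (0.73); in 1 fit of all 54 libraries RNU4-2 was not called (0.86). Without OSU+Enza library 2 and vehicle library 3 the split was 17 higher and 82 lower. The 22Rv1 count was 124, 133 and 168 without vehicle libraries 1, 2 and 3 and 139 without OSU+Enza library 2. The C4-2 count was 661 without vehicle library 2 and 658 without OSU+Enza library 1. The interaction of OSU with Enza had 0 calls by limma in LNCaP, C4-2 and 22Rv1, with 895, 673 and 853 genes at an unadjusted p under 0.05, and 0 by voom in each; without LNCaP vehicle library 1 it had 12 in LNCaP.

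E2 and OSU, both at 100 nM for 12 h, were compared directly, and KLK3, FKBP5 and GREB1 were higher with E2 in each line. KLK3 was higher with E2 than with OSU by 0.61 ± 0.04 in LNCaP, 0.31 ± 0.05 in C4-2 and 1.25 ± 0.11 in 22Rv1. In the same order of lines, FKBP5 was higher by 2.56 ± 0.06, 1.45 ± 0.05 and 2.30 ± 0.05. GREB1 was higher by 1.51 ± 0.09, 1.00 ± 0.07 and 0.61 ± 0.08. DAPK1 was lower with E2 than with OSU in LNCaP (-2.27 ± 0.10), PLD1 in C4-2 (-1.23 ± 0.09) and FOSB in 22Rv1 (-1.47 ± 0.15). SYT4, which fell with each agent in LNCaP, did not differ detectably between them there (E2 minus OSU 0.01, 95% interval -0.07 to 0.08, adjusted p = 0.901), and neither did ESR2 (E2 minus OSU -0.12 in LNCaP, -0.45 to 0.20). The glucocorticoid-shared list had 11 higher and 0 lower of 12 in LNCaP, 6 higher and 0 lower of 12 in C4-2 and 9 higher and 1 lower of 12 in 22Rv1 with E2 relative to OSU. Adjusted over the list alone the counts were 11 higher and 0 lower, 7 higher and 2 lower and 10 higher and 1 lower (adjusted p = 0.000582, 0.00136 and 0.000164 with an estimated correlation). The test called 3512 genes in LNCaP (1829 higher with E2, 1683 lower), 834 in C4-2 (413 and 421) and 3267 in 22Rv1 (1958 and 1309). The splits became 1106 higher and 2793 lower, 564 higher and 310 lower and 813 higher and 1801 lower at total read scaling, 604 higher and 322 lower in C4-2 and 1219 higher and 1413 lower in 22Rv1 after cyclic loess. The split was 317 higher and 197 lower in C4-2 without the libraries that stand apart. The C4-2 count was 515 without E2 library 3 and 535 without OSU library 3. The 22Rv1 count was 1955 and 1870 without E2 libraries 1 and 2, and 1866 and 2111 without OSU libraries 1 and 3.

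Calls with E2 and with OSU against the same vehicle could be compared for LNCaP alone, where 1 of the 2 OSU calls went with E2 and 1 against it (0.233 and 0.266 by independent lists; 0.1 in the same direction in simulated unchanged groups). Over all genes the E2 and OSU fold changes had r = 0.20, 0.26 and 0.24 in LNCaP, C4-2 and 22Rv1. Unchanged groups simulated as above, with a drawn control in place of vehicle, gave mean r of 0.50, 0.47 and 0.50. The observed r lay within 95% of the draws (0.13 to 0.77, 0.05 to 0.77 and 0.19 to 0.73). The covariance was 0.00497, 0.00421 and 0.00552 against means of 0.00489, 0.0051 and 0.00568 simulated, also within 95% of the draws (0.00105 to 0.00917, 0.000459 to 0.012 and 0.00137 to 0.0108), a difference of 7.48e-05, -0.00089 and -0.000157. Part of the excess of r over 0 may come from the shared controls, which cannot be divided into parts of 2 libraries.

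**Figure D3:**
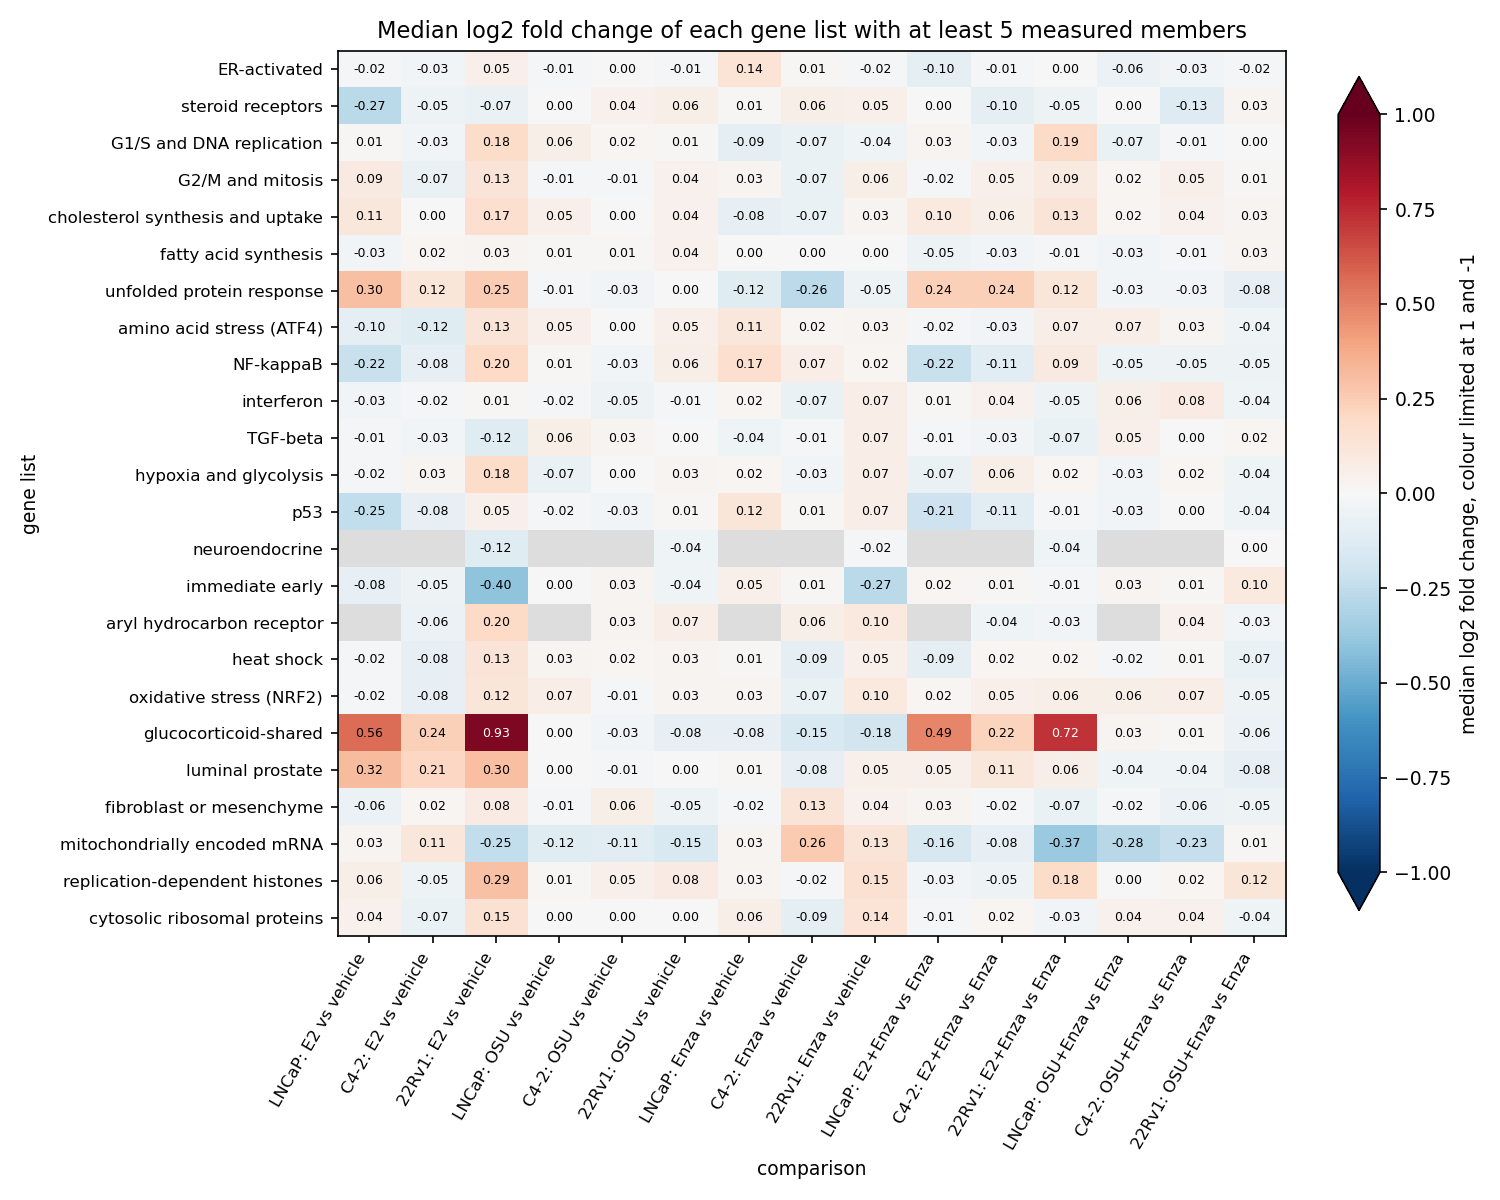
Median log2 fold change of each gene list reported here with at least 5 measured members (y axis) in 15 comparisons (x axis), coloured from blue (lower) to red (higher) with the value printed; grey cells had fewer than 5 members. The glucocorticoid-shared list stands at 0.56, 0.24 and 0.93 with E2 and at 0.00, -0.03 and -0.08 with OSU in LNCaP, C4-2 and 22Rv1.

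The remaining lists are given for LNCaP, C4-2 and 22Rv1 in that order, with the set test's adjusted p. With E2, steroid receptors had 4, 1 and 1 members lower and none higher (adjusted p = 0.0104, 0.285 and 0.318; 0.197 in LNCaP with an estimated correlation), and G2/M and mitosis 9, 0 and 10 higher (adjusted p = 0.245, 0.668 and 0.673 with an estimated correlation). Amino acid stress (ATF4) genes had 8 lower in LNCaP and 6 in C4-2 but 8 higher in 22Rv1 (adjusted p = 0.378, 0.288 and 0.402 with an estimated correlation), and NF-kappaB genes 5 and 2 lower and 3 higher (0.532, 0.9 and 0.376 likewise). Hypoxia and glycolysis genes had 1, 1 and 8 higher (adjusted p = 0.985, 0.638 and 0.459 with an estimated correlation), in LNCaP with a median of -0.02 and a mean of 0.13, where NDRG1 rose by 2.42 ± 0.10. TGF-beta genes had 4 higher and 3 lower, 3 higher and 0 lower and 3 higher and 7 lower (adjusted p = 0.728, 0.418 and 0.522 with an estimated correlation; the medians of -0.01 in LNCaP and -0.03 in C4-2 and the means of 0.14 and 0.14 differ in sign). With the preset correlation, no set call was made in any line for fatty acid synthesis (adjusted p = 0.929, 0.354 and 0.539), interferon (0.515, 0.751 and 0.511), oxidative stress (NRF2) (0.604, 0.282 and 0.165) or fibroblast or mesenchyme markers (0.275, 0.55 and 0.466). Heat shock genes had no set call (adjusted p = 0.761, 0.0753 and 0.061; medians -0.02, -0.08 and 0.13), but in C4-2 and 22Rv1 this depended on the setting. In C4-2 they were called as lower without the filter (0.0379), with voom (0.0471), at total read scaling (0.0306) and in 1 fit of all libraries (0.0462). In 22Rv1 they were called as higher without the filter (0.0275), after TMM rescaling (0.0494), with voom (0.0353) and in 1 fit of all libraries (0.0393). Cytosolic ribosomal protein genes had 1, 0 and 7 higher (adjusted p = 0.867, 0.759 and 0.692 with an estimated correlation). Aryl hydrocarbon receptor genes had no set call in C4-2 (adjusted p = 0.464) or 22Rv1 (0.155), and neuroendocrine genes none in 22Rv1 (0.0565); with fewer than 5 members measured in the other lines they had no test there. Leaving out 1 library gave a call for neuroendocrine genes in 22Rv1 without vehicle library 1 (adjusted p = 0.0395), E2 library 1 (0.0332) or E2 library 2 (0.0305), for heat shock genes in C4-2 without vehicle library 2 (0.0438) or E2 library 2 (0.0394), for TGF-beta genes in 22Rv1 without E2 library 2 (0.0276), and for cytosolic ribosomal protein genes in LNCaP without vehicle library 3 (0.000775). With all libraries, TGF-beta genes were also called in 22Rv1 after cyclic loess (0.0239), and NF-kappaB genes in 22Rv1 at total read scaling (0.0298) and after cyclic loess (0.0106), against preset values of 0.0757 and 0.0864. Basal or squamous epithelium had 3, 1 and 2 members measured and leukocyte markers 2, 2 and 3, too few for a test. Adjusted over the list alone, the counts of higher and lower members in LNCaP were 0 and 4 for steroid receptors, 14 and 0 for G2/M and mitosis, 2 and 9 for amino acid stress, 2 and 5 for NF-kappaB, and 1 and 1 for hypoxia and glycolysis.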

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

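The tests of the E2 response in 22Rv1 against expression level and against the OSU libraries were chosen only after the result was seen; the tests of differences between lines and the splits of the libraries were planned.

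The E2 effect differed between the lines for 4671 of 16026 genes and the Enza effect for 2125. Of 100 splits drawn, the real one included, 3 gave as many for E2, with 5469 as the highest other, and 2 for Enza, with 2489. These splits mix treatment groups and so carry effects of their own, so they decide nothing on chance; the smallest adjusted p by limma was 2.19e-23 for E2 and 4.27e-28 for Enza.

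By gene, what drew attention was a test of the difference between lines in the effect of the same agent. The E2 effect on KLK3 differed most between 22Rv1 and C4-2, by 0.73 (log2), and that on FKBP5 by -1.13 in C4-2 relative to LNCaP. In 22Rv1 relative to LNCaP it differed by -1.41 for MAF and 2.33 for DAPK1, and relative to C4-2 by -1.14 for EGR1. The Enza effect in 22Rv1 relative to LNCaP differed by 1.60 for TMPRSS2 and 1.89 for CHRNA2, and relative to C4-2 by 1.53 for SLC45A3.

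With E2 in 22Rv1 many genes were called as higher by small amounts at the authors' scaling. Among them were 46 of 63 measured members of the G1/S and DNA replication, cholesterol and histone lists. Over all genes the excess of higher calls turned to an excess of lower calls at total read scaling and after cyclic loess. Vehicle libraries that stand apart are argued against as the whole cause: 35 of the 46 were also higher with E2 than with OSU, a comparison without vehicle. That comparison has the same E2 libraries, so it decides nothing on those. By list, 16 G1/S, 12 histone and 8 cholesterol genes were higher with E2 than with OSU, and 16, 17 and 13 than with vehicle. A trend of fold change with expression level (r = 0.30 over 14866 genes, which are not independent replicates) stays open, since 23 of the 46 were still called after cyclic loess, a value between the bounds set for either reading. At total read scaling 26 were called. An effect of E2 itself stays open too.

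For comparisons of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05. For these the real count and the highest of the other splits were as follows, with the real split alone (1 of 10) reaching its count unless a number is given. In LNCaP they were 3551 and 0 for E2, 2 and 56 for OSU (3 of 10), 2911 and 13 for Enza, 1058 and 0 for E2+Enza, 4229 and 0 for OSU+Enza, 3291 and 0 for E2+Enza against Enza, 14 and 4 for OSU+Enza against Enza, and 3512 and 1 for E2 against OSU. In C4-2 they were 817 and 0, 0 and 1 (10 of 10), 1184 and 0, 11 and 1, 1036 and 0, 1035 and 0, 0 and 0 (10 of 10), and 834 and 0, in that order. In 22Rv1 they were 4118 and 0, 0 and 0 (10 of 10), 98 and 1, 2055 and 0, 296 and 0, 1180 and 3, 15 and 39 (2 of 10), and 3267 and 0. Between vehicle libraries they were 10697 and 5 for C4-2 against LNCaP and 13355 and 0 for 22Rv1 against LNCaP. The 56 and 39 calls of other splits, for OSU in LNCaP and for OSU+Enza against Enza in 22Rv1, point to a structure of those samples other than the treatment.

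For the interaction of E2 with Enza, 3 of 100 drawn splits gave as many calls as the real 1290 in LNCaP, 6 as many as 210 in C4-2 and 10 as many as 63 in 22Rv1. The highest others were 3408, 2190 and 4360, several times the real counts, which points to the treatment groups that these splits mix. Because such splits carry effects of their own, they decide nothing on chance in any of the lines, where the smallest adjusted p by limma was 1.24e-19, 3.61e-11 and 2.75e-07. For the interaction of OSU with Enza, with 0 real calls, all 100 did, with 4354, 612 and 92 as the highest others, and for the difference of the OSU effect between lines all 100 did, with 2; by limma 895, 673, 853 and 471 genes had an unadjusted p under 0.05, and voom called 0 in each.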

How the results depend on the processing

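Voom, total read scaling, cyclic loess and leaving out the libraries that stand apart were chosen only after the results were seen; the other alternatives were planned, and the planned count test was not run. Another pseudocount (0.1) left each of the 36 counts within 1.5 times its value, and each of the 163 named fold changes and 82 list tests on its side of the threshold. Of the counts, 33 stayed within 1.5 times without the filter, 34 after TMM rescaling, 33 with voom, 31 at total read scaling and 33 after cyclic loess. Over all fits with 1 library left out, 241 counts stayed within 1.5 times and 77 moved, and a named fold change lost its call in 24. Named fold changes lost their call in 5 cases without the filter, 3 with voom, 2 at total read scaling and 7 in 1 fit of all libraries. An estimated correlation ended the call of 29 of the list tests. The test fry, which asks whether a set's genes move on balance one way and does not compare the set with other genes, ended 8 list calls and gave 11 more, all with E2 (adjusted p after each list): in 22Rv1 for NF-kappaB (0.000151), aryl hydrocarbon receptor (0.00114), fatty acid synthesis (0.014), fibroblast or mesenchyme (0.000136), heat shock (0.0184), interferon (0.00106), neuroendocrine (0.00247) and oxidative stress (NRF2) (0.00125), LNCaP for TGF-beta (0.000625) and fibroblast or mesenchyme (0.00389) and C4-2 for steroid receptors (0.0127). The counts that moved are given from the value above to the alternative; the cause was not tested.

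Without the filter, the count moved from 2 to 0 for LNCaP OSU, from 15 to 1 for 22Rv1 OSU+Enza against Enza and from 63 to 35 for 22Rv1 E2 by Enza. With voom, the count moved from 2 to 0 for LNCaP OSU, from 0 to 2 for C4-2 OSU+Enza against Enza and from 15 to 9 for 22Rv1 OSU+Enza against Enza. At total read scaling, the count moved from 2 to 1 for LNCaP OSU, from 11 to 20 for C4-2 E2+Enza, from 0 to 2 for C4-2 OSU+Enza against Enza and from 63 to 39 for 22Rv1 E2 by Enza. In the same setting it moved from 19 to 33 for the mean OSU effect. In 1 fit of all 54 libraries, the count moved from 2 to 0 for LNCaP OSU, from 1058 to 657 for LNCaP E2+Enza, from 14 to 2 for LNCaP OSU+Enza against Enza and from 1290 to 832 for LNCaP E2 by Enza. In the same setting it moved from 0 to 1 for C4-2 OSU, from 11 to 27 for C4-2 E2+Enza, from 0 to 1 for C4-2 OSU+Enza against Enza and from 210 to 363 for C4-2 E2 by Enza. In the same setting it moved from 0 to 1 for C4-2 OSU by Enza, from 0 to 6 for 22Rv1 OSU, from 98 to 189 for 22Rv1 Enza and from 296 to 553 for 22Rv1 OSU+Enza. In the same setting it moved from 15 to 86 for 22Rv1 OSU+Enza against Enza, from 63 to 152 for 22Rv1 E2 by Enza and from 0 to 7 for 22Rv1 OSU by Enza. After TMM rescaling, the count moved from 11 to 22 for C4-2 E2+Enza and from 0 to 2 for C4-2 OSU+Enza against Enza. After cyclic loess, the count moved from 11 to 35 for C4-2 E2+Enza, from 15 to 28 for 22Rv1 OSU+Enza against Enza and from 19 to 101 for the mean OSU effect. Without the libraries that stand apart, the count moved from 817 to 396 for C4-2 E2, from 1184 to 751 for C4-2 Enza, from 210 to 96 for C4-2 E2 by Enza and from 834 to 514 for C4-2 E2 against OSU. In the same setting it moved from 296 to 99 for 22Rv1 OSU+Enza, from 15 to 5 for 22Rv1 OSU+Enza against Enza, from 63 to 109 for 22Rv1 E2 by Enza and from 4671 to 2587 for E2 between lines. In the same setting it moved from 19 to 11 for the mean OSU effect.

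With each library left out in turn, counts in LNCaP ranged from 0 to 12 for OSU, 0 to 12 for OSU by Enza, 568 to 1389 for E2+Enza and 6 to 15 for OSU+Enza against Enza. With each library left out in turn, counts in C4-2 ranged from 521 to 868 for E2, 609 to 1081 for Enza, 3 to 34 for E2+Enza, 106 to 332 for E2 by Enza and 658 to 817 for OSU+Enza. Other counts in C4-2 ranged from 515 to 965 for E2 against OSU and 0 to 1 for OSU+Enza against Enza. With each library left out in turn, counts in 22Rv1 ranged from 2193 to 3999 for E2, 55 to 410 for Enza, 856 to 1888 for E2+Enza, 124 to 440 for OSU+Enza and 21 to 350 for E2 by Enza. Other counts in 22Rv1 ranged from 1866 to 3263 for E2 against OSU and 0 to 26 for OSU+Enza against Enza. With each library left out in turn, counts in tests over lines ranged from 0 to 1 for OSU between lines, 1229 to 2777 for Enza between lines, 2952 to 5174 for E2 between lines and 12 to 32 for the mean OSU effect. Leaving out a library compares 2 with 3.

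The replicate numbers do not pair the libraries. Deviations of libraries with the same number had mean correlations of 0.0163, -0.0102 and 0.00435 in LNCaP, C4-2 and 22Rv1 (ranges -0.14 to 0.26, -0.51 to 0.43 and -0.31 to 0.25), and 7, 8 and 9 of 18 libraries correlated best with their own number, so not every sample did. With the replicate number as a block, the count moved from 2 to 1 for LNCaP OSU, from 15 to 9 for 22Rv1 OSU+Enza against Enza and from 0 to 1 for OSU between lines; it moved no other count by over 1.5 times, and 2 named fold changes lost their call.

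Among lists, direction turned with a call before or after in 2: cytosolic ribosomal proteins with E2 in C4-2 without the libraries that stand apart (adjusted p = 0.966), and mitochondrially encoded mRNA in 22Rv1 with OSU+Enza against Enza without Enza library 3 (adjusted p = 0.00676, in a range of 0.00616 to 0.685 over the libraries left out); the cause was not tested. With no call before or after, it turned in 14 tests with 1 library left out, 4 after cyclic loess, 2 with fry, 1 without the libraries that stand apart and 2 at total read scaling. Depth limits low genes such as ESR2, with 47 to 134 reads per library.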

Other observations

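The tests of variation between libraries in mitochondrial mRNA, of small RNA, of SYT4 and of E2+Enza against E2 were chosen only after the result was seen. The mean OSU effect was added after the comparisons of single groups had been seen, with its bounds written before its own result; the test of scaling in mitochondrial mRNA was also written before.

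The mean OSU effect over the 3 lines and both Enza states was called for 19 of 16026 genes by limma, 3 higher and 16 lower, with 1584 at an unadjusted p under 0.05 and 17 called by voom. KLK2 fell (-0.19 ± 0.02, adjusted p = 1.74e-08), as did STEAP2 (-0.14 ± 0.02), STEAP1 (-0.14 ± 0.02), SYT4 (-0.19 ± 0.02), KLK3 (-0.19 ± 0.03, adjusted p = 0.000131) and MAOA, a monoamine oxidase (-0.10 ± 0.02), each lower in 6 of 6 comparisons, and DHRS2 rose (0.22 ± 0.04). These genes were chosen after their values were seen. Of 100 drawn splits, the real one included, 2 gave as many, the highest other 20. The mean effect was added after KLK3, KLK2 and SYT4 had been seen lower with OSU added to Enza in the same LNCaP libraries. For that reason the splits decide nothing on chance. An effect of OSU-ERb-12 shared by the lines may underlie the calls, but 19 lies between the bounds of 10 and 50 set for either reading. The count was 33 at total read scaling and 101, past the upper bound, after cyclic loess, so it depends on the scaling and stays open. The count was 12 without LNCaP vehicle library 1, 29 without 22Rv1 Enza library 3 and 32 without 22Rv1 OSU+Enza library 1. For SYT4 alone the permutation p was 1e-05, the smallest the permutations can give, but SYT4 was picked for being lower, so this test decides nothing.

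Mitochondrially encoded mRNA lay lower with OSU than its control in 6 of 6 comparisons of mean log2 level (mean difference -0.16, from -0.28 to -0.02). A two-sided permutation test within the 6 pairs of groups gave p = 0.0071, but the list was picked for being lower, so this test decides nothing and variation between libraries of one group stays open. Scaling of the libraries stays open: at total read scaling 5 of the 6 medians were negative, and they moved too little from their values at the authors' scaling to decide. In 22Rv1 with Enza the median fold change of the list was 0.01, against the -0.02 of the mean level, and the set was called in the other direction without Enza library 3 (adjusted p = 0.00676). The mitochondrial ribosomal RNA RNR2, not called, had a lower mean with OSU in each line without Enza and in LNCaP with Enza; RNA quality and ribosomal RNA depletion were not tested, nor was a biological explanation beyond OSU itself, and these stay open.

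Small nuclear and nucleolar RNA was higher in 22Rv1 with OSU+Enza than with vehicle for 7 of 169 tested, where their share of the 99 higher calls would give 1.13. It was called lower for 1. Of the 7, 6 were still called higher at total read scaling and 6 after cyclic loess, so most calls did not depend on these choices. Reads over the authors' effective sizes were 0.895 to 0.924 in the vehicle libraries and 0.921 to 0.98 with OSU+Enza. Total read scaling therefore moved fold changes too little to decide on scaling, which stays open. A single library is a candidate source: without OSU+Enza library 2, 1 was still called, and the median log2 fold change of the 7 went from 0.83 to 0.60, with 2 libraries in place of 3. The yield of small RNA in that library's preparation was not measured otherwise.

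E2+Enza and E2 alone differed for 1928 genes in LNCaP (894 higher with E2+Enza, 1034 lower), 486 in C4-2 (201 and 285) and 178 in 22Rv1 (20 and 158) by limma.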
